A study of Rattus norvegicus with 24 samples.

How the data were processed

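Plantaris muscle of female rats of the HRT and LRT lines, with and without 14 days of functional overload, was homogenised and total RNA was made into Illumina TruSeq libraries, per the labels' protocols. Groups came from the line and treatment labels, and all 24 libraries were used. The labels do not say whether control muscles came from separate animals or from the unoperated leg of the overloaded ones. Nor do they say that same-numbered libraries share an animal, and p-values measure the spread between these samples. The deposited table holds estimated counts per gene, not normalized, for 31998 Ensembl gene IDs. The submitters' processing notes name Salmon 0.9.1 and the builds Rnor_6.0 and rn6. The annotation, the settings and how reads shared between similar genes were divided are not given in the sources used here. In the deposited estimated counts, 2.62% of values of at least 1 lay within 0.001 of a whole number. Estimated counts divide ambiguous reads between genes, so values of near-identical genes are uncertain.

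Estimated counts were rounded to whole numbers. Of the genes, 4208 had a total of 0, and edgeR's filterByExpr (minimum count 10, minimum total 15) kept 16661 and left out 15337. In R 4.3.3 with edgeR 4.0.16, counts were scaled by trimmed mean of M values (TMM), and 1 quasi-likelihood model with a coefficient per group was fitted to all libraries with robust dispersion. Contrasts were tested with the quasi-likelihood F-test and Benjamini-Hochberg adjustment, with a threshold of 0.05. The 5 contrasts were overload against control in each line, the difference between these responses, and LRT against HRT in each state. CPM values are counts scaled to a common library total after TMM. Standard errors of log2 fold changes are approximate, computed as the absolute log2 fold change over the square root of F. Library totals ran from 26997674 to 34254957 counts and entered each fit through the scaling. Intervals over libraries are 95% bootstrap intervals. A group with 0 counts was given a floor of 3 counts per library, which covers counting error only.

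These tests, the alternatives to them and the rule for named genes were fixed before the data were examined. That rule took genes past the threshold with a mean log2 CPM of at least 1 and the largest changes in each direction. It asked for genes with symbols, for fixed genes and for members of 38 gene lists (pathways, fibre types and cell types). The gene name table used here covers 47357 genes of another assembly, GRCr8, and 0 IDs matched. The 38 lists and the fixed genes were therefore not tested, the condition on symbols was dropped, and 2 IDs per direction are printed. The reference table's coordinates were not used.

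No libraries were duplicates: over 60 pairs within groups and 12889 genes, the lowest chi-square per degree of freedom was 13.93. The model was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. Genes were drawn independently, with 1 dispersion per gene for all groups. The real overloaded libraries varied far more than controls, so the rates below may not hold for them. For overload in HRT, 56.72% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 96.97% of those changed 4-fold were recovered among 16440 tested genes, with 9 unchanged genes called. For the difference between responses these were 23.88%, 70.15% and 92.42% among 16502 genes, with 9 unchanged genes called, so small differences in response were often missed in the simulation.

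Alternatives were DESeq2 1.42.0 (Wald test, and its size factors in edgeR), limma-voom (limma 3.58.1), no filter, a stricter filter (1 CPM in 6 libraries and a mean count of 50), dispersion without robust estimation, RIN as a covariate, the replicate number as a block with and without RIN, the compared groups alone, and each library left out in turn. Scaling by library totals, counts not rounded, 1 surrogate variable (sva 3.50.0) and the overload score with its variants were added after the data had been seen. Exact permutation tests enumerated all 924 splits of 12 libraries and are two-sided. The difference between score responses used 100000 permutations. Splits of the samples were drawn 100 per contrast, with a fixed seed. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.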

Results

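RNA was sequenced from the plantaris, a calf muscle, of female rats of the LRT and HRT lines. These lines were bred for low (LRT) and high (HRT) gains in running capacity with endurance training. The rats were 14 months old and of generation 19. In the overloaded groups the neighbouring gastrocnemius and soleus muscles had been removed on one side, and the plantaris was taken 14 days later. Each of the 4 groups (HRT control, HRT overload, LRT control and LRT overload) had 6 libraries. Library totals ranged from 26997674 to 34254957 estimated counts. Of 31998 genes, 16661 had enough counts to be tested, and these held 99.95% of all reads. The deposited table does not pair its Ensembl gene IDs with gene names, and 0 of them matched the table of names used here. Genes are therefore given by ID, at most 2 per direction in each comparison, and the gene lists fixed for pathways and cell types could not be tested.

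Overloaded muscle used its RNA pool differently from control muscle in both lines. The 10 most abundant genes of each library held 31.1% ± 0.489 (SD, n = 6) of the counts in HRT control and 26.7% ± 2.16 in HRT overload (exact permutation p = 0.00216, two-sided, the smallest that 6 against 6 libraries allow). In LRT they held 31.5% ± 1.25 in control and 29.1% ± 1.24 in overload (exact permutation p = 0.00649). More genes were detected after overload, 21486 ± 425 against 20492 ± 214 in HRT (exact permutation p = 0.00216) and 21313 ± 384 against 20884 ± 244 in LRT (exact permutation p = 0.0152). The first principal component held 57.05% of the variance. Control libraries lay between −59.95 and −43.74 on it, LRT overload libraries between 13.87 and 67.55, and HRT overload libraries between 33.23 and 87.27. RNA integrity moved with overload. The RNA integrity number (RIN) was 8.27 ± 0.216 in HRT control and 8.97 ± 0.327 in HRT overload (exact permutation p = 0.00649), and 8.28 ± 0.147 in LRT control and 8.67 ± 0.258 in LRT overload (exact permutation p = 0.0216). Library totals averaged 31938649 ± 1354951 counts in LRT control and 30181651 ± 1079448 in LRT overload (exact permutation p = 0.0346), and 29845221 ± 2376503 in HRT control and 31545998 ± 1748354 in HRT overload (exact permutation p = 0.193). Over the 16 exact permutation tests of these 4 measures, the difference in LRT totals had a Benjamini-Hochberg adjusted p of 0.0692, and the adjusted p of the other differences given here as under 0.05 lay between 0.0173 and 0.0494.

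The first comparison asked what overload changed in HRT muscle. ENSRNOG00000002548 rose from 0.227 ± 0.116 CPM (read counts scaled to a common library total; SD, n = 6) to 277 ± 257, a log2 fold change of 10.21 ± 1.12 (SE; edgeR adjusted p = 1.34e-07). ENSRNOG00000028992 rose from 0.128 ± 0.0686 to 60.2 ± 57.0 CPM (log2 fold change 8.81 ± 1.18, edgeR adjusted p = 1.81e-06). The control levels of both rest on few reads, 2 to 11 and 1 to 7 per library. Over 25 other settings both calls held, with log2 fold changes of 8.43 to 11.58 and of 7.68 to 10.73. ENSRNOG00000016043 fell from 194 ± 48.2 to 28.5 ± 11.1 CPM (log2 fold change −2.76 ± 0.229, edgeR adjusted p = 1.2e-09). ENSRNOG00000050625 fell from 45.6 ± 6.39 to 6.98 ± 2.92 CPM (log2 fold change −2.71 ± 0.277, edgeR adjusted p = 3.17e-08). Its call was lost in a fit with the replicate number as a block and RIN as a covariate (log2 fold change −2.05, edgeR adjusted p = 0.152; ranges over 25 settings −2.89 to −2.05 and 1.1e-23 to 0.152). In all, 10523 genes changed, 5319 upward and 5204 downward. Large changes were mostly upward: 2554 genes rose and 530 fell by more than 2-fold, and 805 rose and 35 fell by more than 4-fold. Among the 100 most abundant genes 74 fell and 9 rose. With libraries scaled by their totals alone, 7942 genes rose and 2238 fell, the median gene moved by 0.27 on the log2 scale, and among those 100 genes 60 fell and 16 rose.

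The same comparison in LRT muscle had the same shape. ENSRNOG00000002548 rose here too, from 0.291 ± 0.114 to 83.3 ± 71.0 CPM (SD, n = 6; log2 fold change 8.15 ± 1.06, edgeR adjusted p = 2.07e-06). ENSRNOG00000030187 had 0 counts in each of the 6 LRT control libraries and a mean of 15.4 ± 23.8 CPM after overload. The rise rested on 3 of the 6 overloaded libraries, at 6.19, 26.6 and 59.4 CPM, while the other 3 were at 0.0969, 0.0992 and 0.2 CPM, near the floor of 0.107 CPM that 3 counts per library give. Against this floor the mean was at least 145-fold higher and the median at least 29.9-fold higher. Its edgeR adjusted p was 0.00168, and limma-voom did not call it (adjusted p = 0.103). ENSRNOG00000019009 fell from 54.1 ± 14.7 to 11.4 ± 5.36 CPM (log2 fold change −2.25 ± 0.257, edgeR adjusted p = 2.74e-07). ENSRNOG00000016685 fell from 3.62 ± 2.74 to 0.864 ± 0.347 CPM (log2 fold change −2.07 ± 0.396, edgeR adjusted p = 0.000119). ENSRNOG00000030187 also rose in HRT (log2 fold change 8.32, edgeR adjusted p = 0.00395), from 0 to 2 counts per control library. ENSRNOG00000019009 and ENSRNOG00000016685 also fell in HRT (log2 fold changes −2.29 and −1.72, edgeR adjusted p = 1.48e-07 and 0.000609). In all, 9524 genes changed in LRT, 4808 upward and 4716 downward. By more than 2-fold, 2150 rose and 193 fell. Among the 100 most abundant genes 58 fell and 8 rose. Scaling by totals alone gave 6765 genes higher and 1893 lower, with a median shift of 0.222, and 45 of those 100 genes lower and 15 higher.

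Across genes, which are not independent replicates, the responses of the 2 lines ran together. The log2 fold changes correlated with Pearson's r = 0.899 and Spearman's rho = 0.863 over 16661 genes, and 85.2% had the same sign. The lines share no libraries. In both lines 4247 genes rose, where independent lists would share 1535, and 3763 fell, where independent lists would share 1473. Opposite changes past the threshold were found for 10 genes that rose in HRT and fell in LRT and for 5 genes the other way. Of these, ENSRNOG00000027061 alone passed the test of the difference between responses, given below. Of the 8010 genes changed in the same direction, 65.92% had the larger change in HRT. Of the 2499 among them with a mean change over 2-fold, it was 76.63%. The slope of the long axis of the points (LRT over HRT responses, not a regression) was 0.839. A 95% bootstrap interval over libraries was 0.667 to 1.04, which includes equal responses. The interval was computed from differences of mean log2 CPM, not from the edgeR fold changes behind the 0.839.

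**Figure D1:**
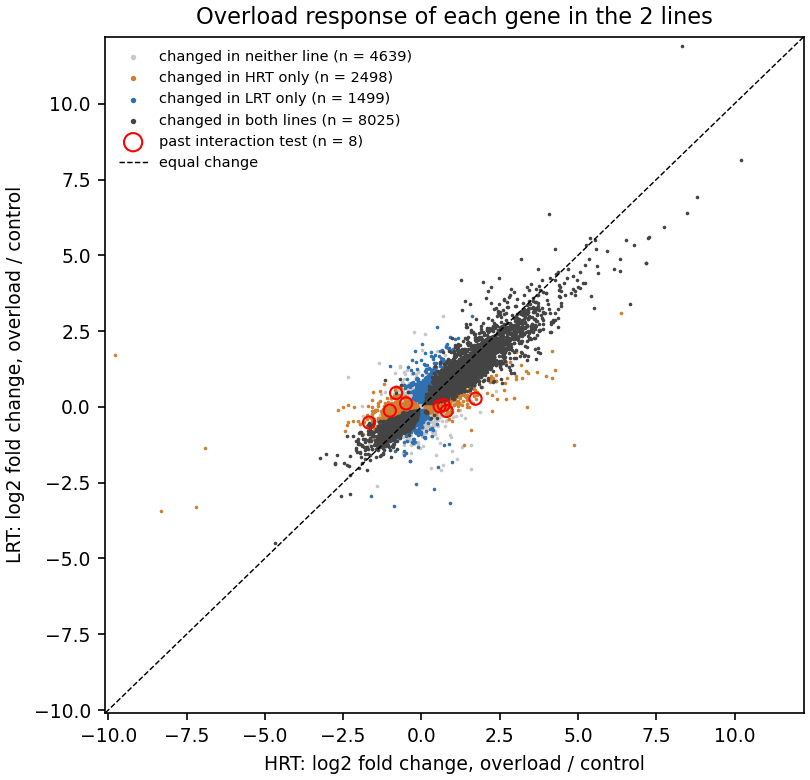
Each point is 1 of 16661 genes, with its log2 fold change (overload over control) in HRT on the horizontal axis and in LRT on the vertical axis. Colours give the lines in which it passed an edgeR adjusted p of 0.05, red circles mark the 8 genes past the interaction test, and the dashed line marks equal change. In both lines 85.2% of genes have the same sign, and fitted values of genes at 0 counts in a group, such as ENSRNOG00000030187 (the highest point), depend on the prior count.

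The difference between the responses was then tested gene by gene. ENSRNOG00000015225 rose in HRT from 11.4 ± 0.799 to 19.9 ± 2.12 CPM (SD, n = 6; log2 fold change 0.81, edgeR adjusted p = 1.22e-08). In LRT it was 16.4 ± 1.72 in control and 15 ± 1.29 after overload (edgeR adjusted p = 0.154). The difference between these responses, LRT minus HRT, was −0.94 ± 0.113 on the log2 scale (SE; edgeR adjusted p = 0.000234). ENSRNOG00000013018 more than tripled in HRT, from 13.1 ± 2.97 to 43.5 ± 5.77 CPM, and was 25 ± 9.06 and 30.1 ± 6.18 CPM in LRT (difference −1.46 ± 0.268, edgeR adjusted p = 0.046). ENSRNOG00000027061 fell in HRT from 3.87 ± 0.699 to 2.21 ± 0.257 CPM and rose in LRT from 2.10 ± 0.461 to 2.90 ± 0.701 CPM (difference 1.27 ± 0.233, edgeR adjusted p = 0.046). ENSRNOG00000052669 fell further in HRT, from 6.04 ± 0.906 to 1.89 ± 0.406 CPM, than in LRT, from 4.67 ± 0.964 to 3.27 ± 0.558 CPM (difference 1.16 ± 0.22, edgeR adjusted p = 0.046). In all, 8 genes passed, 4 in each direction, and 2265 genes had an unadjusted p under 0.05. Scaling by totals alone gave 6 genes, 1 higher and 5 lower. Of 2498 genes that changed in HRT alone, 6 passed the interaction test, and of 1499 that changed in LRT alone, 0 did (edgeR). The count of 8 was not stable: it ran from 1 to 25 as single libraries were left out and was 150 with the DESeq2 Wald test. ENSRNOG00000015225 passed in 35 of 36 other settings, against 13 for ENSRNOG00000027061, 12 for ENSRNOG00000013018 and 10 for ENSRNOG00000052669. The differences of these last 3 genes kept their sign over the 36 settings, at 1.06 to 1.36, −1.54 to −0.99 and 0.91 to 1.25. In control muscle the lines differed, LRT minus HRT, by 0.53 (ENSRNOG00000015225), 0.93 (ENSRNOG00000013018), −0.88 (ENSRNOG00000027061) and −0.37 (ENSRNOG00000052669). The edgeR adjusted p were 0.00125, 0.0111, 0.00542 and 0.208. After overload these line differences were −0.41, −0.53, 0.39 and 0.79 (edgeR adjusted p = 0.0071, 0.105, 0.163 and 0.00999).

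**Figure D2:**
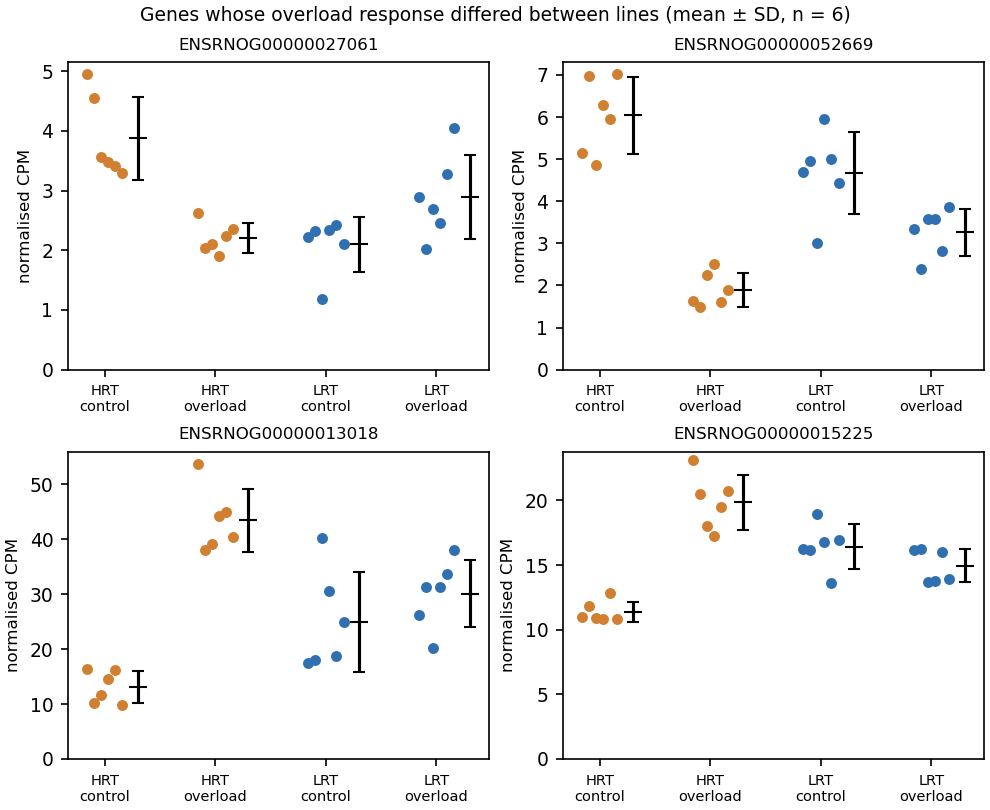
Normalised CPM of the 4 named genes past the interaction test, with 1 point per library (6 per group, HRT orange and LRT blue) and the mean ± SD beside the points. In the panel of ENSRNOG00000015225 the HRT means are 11.4 and 19.9 CPM and the LRT means 16.4 and 15 CPM, in control and overloaded muscle.

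In control muscle, ENSRNOG00000042253 was higher in LRT, at 12 ± 0.644 CPM against 3.22 ± 0.367 in HRT (SD, n = 6; log2 fold change 1.89 ± 0.117, edgeR adjusted p = 2.73e-10). ENSRNOG00000028598 was at 4.25 ± 0.844 against 1.28 ± 0.559 CPM (log2 fold change 1.73 ± 0.263, edgeR adjusted p = 0.00125). ENSRNOG00000011323 was lower in LRT, at 1.42 ± 0.841 against 12.6 ± 5.02 CPM (log2 fold change −3.15 ± 0.578, edgeR adjusted p = 0.00542). ENSRNOG00000038999 was at 6.01 ± 1.52 against 49.1 ± 20.5 CPM (log2 fold change −3.03 ± 0.578, edgeR adjusted p = 0.00706). In all, 328 genes differed between lines, 203 higher and 125 lower in LRT, and 29 and 25 of these by more than 2-fold. With libraries scaled by their totals alone, 76 genes were higher and 186 lower. The count was 623 with the DESeq2 Wald test, and with single libraries left out it ran from 154, without HRT control replicate 4, to 495, without LRT control replicate 2, with 7 of 12 libraries moving it over 1.5 times.

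In overloaded muscle, ENSRNOG00000029954 was higher in LRT, at 78.8 ± 9.63 CPM against 18.1 ± 7.55 in HRT (SD, n = 6; log2 fold change 2.12 ± 0.289, edgeR adjusted p = 0.000368). This gene was higher in LRT control muscle as well (log2 fold change 1.36, edgeR adjusted p = 0.012), and it did not pass the interaction test (edgeR adjusted p = 0.399). After overload ENSRNOG00000056973 was at 6.62 ± 2.89 CPM in LRT against 1.11 ± 1.49 in HRT (log2 fold change 2.57 ± 0.618, edgeR adjusted p = 0.0284). Its call was lost in 9 of 23 other settings, 7 of them with a single library left out, and its log2 fold change ran from 2.32 to 4.11 (limma-voom) over these settings. ENSRNOG00000019050 was lower in LRT, at 0.462 ± 0.0888 against 12.5 ± 13.5 CPM (log2 fold change −4.75 ± 0.899, edgeR adjusted p = 0.00719), and limma-voom did not call it (adjusted p = 0.128). Its line difference in control muscle was −2.99 (edgeR adjusted p = 0.083). Its HRT overload libraries ran from 0.298 CPM in replicate 5, below each LRT overload library, to 37.3 CPM in replicate 6, without which the log2 fold change was −4.01 (edgeR adjusted p = 0.0194). ENSRNOG00000038999, lower in LRT control muscle as well, was at 13.7 ± 11 against 92.2 ± 56.8 CPM (log2 fold change −2.74 ± 0.555, edgeR adjusted p = 0.0123). In all, 514 genes differed, 266 higher and 248 lower in LRT. Scaling by totals alone gave 225 higher and 1928 lower. With single libraries left out the count ran from 171, without LRT overload replicate 3, to 1647, without HRT overload replicate 3, and a fit to these 2 groups alone gave 115, in which neither ENSRNOG00000056973 nor ENSRNOG00000038999 passed. For control muscle a fit to its 2 groups alone gave 491, so the order of the 2 counts turned. The main model shares 1 dispersion per gene over all groups, although overloaded libraries varied more than controls. Its adjusted p-values for overloaded muscle may therefore be too small.

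In the model of all groups, most line differences were called in 1 state alone, 274 genes in control muscle and 460 in overloaded muscle. Both states called 54 genes, and 53 of these differed in the same direction. A call in 1 state alone does not show a difference between states. The sign was the same in the other state for 77.44% of the genes called in control muscle and 74.51% of those called in overloaded muscle. Both shares include the 54 genes called in both states. Only 8 genes in all passed the interaction test. In LRT 35 of the 53 genes were higher in both states, where independent lists would share 3.24, and 18 were lower, where independent lists would share 1.86. The control and overloaded comparisons use different libraries but may share animals, since the labels do not say where the control muscles came from. Shared animals could also give the same line difference in both states. The 2-fold mark was passed in both states by 16 of the 53 genes.

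The overload response was also summarised as 1 score per library, defined after the spread among overloaded libraries had been seen. The score is the mean log2 change from control over 2366 rising and 284 falling genes, chosen from overloaded against control libraries without regard to line, with falling genes counted as positive and both parts weighted equally. It was 1.63 ± 0.325 (SD, n = 6) in HRT overload and 1.28 ± 0.238 in LRT overload. The difference of 0.349 had a 95% bootstrap interval of 0.0444 to 0.637 and an exact permutation p of 0.0649, two-sided, so it did not pass 0.05. The response of LRT was 81.7% of that of HRT, a difference of 0.292 (permutation p = 0.13). The part from falling genes differed by 0.384 (exact permutation p = 0.0281) and the part from rising genes by 0.314 (exact permutation p = 0.115). Overloaded libraries varied far more than controls, with a variance 51.4 times that of the controls in HRT and 18.7 times in LRT.

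**Figure D3:**
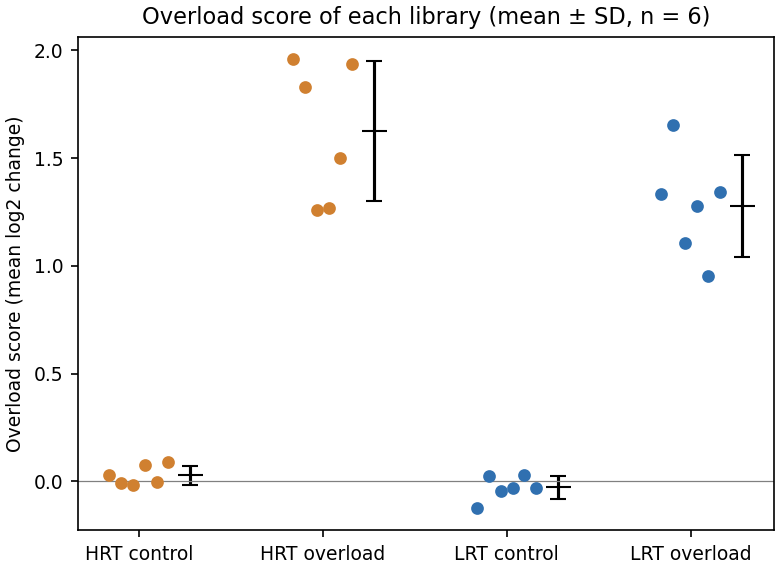
Overload score of each library (mean log2 change from control over the overload genes), by group, with 1 point per library (6 per group) and the mean ± SD beside the points. Overloaded HRT libraries lie between 1.26 and 1.96 and overloaded LRT libraries between 0.953 and 1.65, so the groups overlap.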

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

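Tests of RIN and of other splits of the samples, and the comparison of rising and falling parts, were chosen after their results had been seen. The thinning test and the test of low counts were set out before they were run.

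Overloaded HRT libraries had a higher overload score than overloaded LRT libraries, by 0.349, which did not pass an exact permutation test (p = 0.0649), so chance stays open. RIN averaged 8.97 in HRT overload and 8.67 in LRT overload (exact permutation p = 0.128), but within the overloaded groups the score changed by −0.233 per RIN unit (95% bootstrap interval −0.846 to 0.351), below the slope of 1.16 that the difference would need. An error of scaling would move rising and falling genes the same way and put the rising part near −0.384, while it was 0.314 (interval −0.0254 to 0.65). A weaker response of the LRT line may account for the difference and remains an untested hypothesis, since RIN and scaling are the only technical explanations weighed and a different mix of cells could not be tested without gene names.

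Overloaded libraries of one group spread widely in the score. Neither RIN nor sequencing depth can be told apart from other sources of the spread. Thinning every library to 26997324 counts left the SD within HRT overload at 0.327, against 0.325 before. Within LRT overload it was 0.237, against 0.238 before. The score is a mean over many genes and is already scaled by library totals, so thinning of this size could hardly move it. The thinning test therefore cannot decide whether depth plays a part. Thinning does not bear on other differences that go with library totals. The correlation of score and RIN within overloaded groups was r = −0.241, with opposite signs in HRT (−0.52) and LRT (0.239) (95% bootstrap interval −0.781 to 0.395, permutation p = 0.481; rho = −0.225, permutation p = 0.507; r = −0.271 without the 2 libraries farthest from the median; adjusted p = 0.481 and 0.507 over 2 measures). For total counts r was −0.511, with −0.789 in HRT and 0.0976 in LRT (permutation p = 0.137, adjusted 0.274; rho = −0.343, permutation p = 0.313, adjusted 0.507; r = −0.186 without 2 libraries), and differences in the extent of the response between animals may also account for the spread, untested here.

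For the 53 genes that differed between lines in the same direction in both states, low counts are argued against as the main source: 24.5% (exact Clopper-Pearson interval 13.8 to 38.3) had a mean log2 CPM under 1, against 25.2% of all tested genes. Sequence differences of a line from the reference, which could change how reads are assigned, were not tested and stay open beside a difference in expression.

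Other splits of the samples were drawn, 100 per comparison with the real one included. Chance could be excluded for overload in each line and for lines in control muscle. For overload, 1 split gave as many genes in HRT (9935 in the fit to these groups alone, highest other 5107) and 1 in LRT (8617, highest other 5280). Between lines in control muscle 1 split gave as many (491, highest other 5). In overloaded muscle 2 splits gave as many (115, highest other 1290), and for the difference between responses 3 gave as many as 8 (highest other 1275, next 31). These shares are under 0.05 as drawn, but 100 draws do not bound them closely, and chance is not taken as excluded for these 2 counts. In each of these 2 comparisons 1 drawn split gave over 1000 genes, which points to a structure of the samples. Both splits set overloaded libraries of high score against those of lower score, with means of 1.67 and 1.24 for the split of 1290 genes and 1.7 and 1.2 for that of 1275. This was seen after the splits were drawn and was not tested.

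The overload response differed between lines for 8 genes by the interaction test, among them ENSRNOG00000027061 (1.27 on the log2 scale, LRT minus HRT), ENSRNOG00000052669 (1.16), ENSRNOG00000013018 (−1.46) and ENSRNOG00000015225 (−0.94). Single libraries stood apart from their group in 8 of 91 groups of values tested, where chance flags about 4.55. LRT overload replicate 2 was high in genes detected (22052, next 21379), in its TMM factor (1.18, next 1.05) and in ENSRNOG00000028992 (42.32 CPM, next 15). HRT control replicate 6 had a low TMM factor (0.916, next 0.943). LRT overload replicate 4 was high in ENSRNOG00000011323 (5.265 CPM, next 1.83). LRT control replicate 2 was high in ENSRNOG00000016043 (286.8 CPM, next 217). LRT control replicate 3 was high in ENSRNOG00000016685 (9.07 CPM, next 3.70) and low in ENSRNOG00000027061 (1.19 CPM, next 2.11).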

How the results depend on the processing

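Scaling by library totals, counts not rounded, the surrogate variable and the overload score were chosen after the data had been seen; the cause of a change was not tested unless given. Counts for overload in HRT and LRT stayed within 1.5 times under every setting except the replicate block with RIN, which left 1557 and 5183 genes. RIN was higher after overload in both lines, so this fit can separate RIN from overload only in part. The replicate block alone gave 10218 in HRT, 9109 in LRT and 1 gene for the difference between responses, and 0 with RIN as well. The numbers gave no sign of pairing. Deviations of same-numbered libraries from their group means correlated between −0.0978 and 0.127, 1 of 12 pairs over 0.1, and 3 of 12 overloaded libraries matched their own number best. This cannot exclude shared animals, since overloaded libraries varied far more than controls, which could hide an effect of the animal.

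The 8 genes of the difference between responses became 1 with DESeq2 size factors, 5 with no filter, 5 without robust dispersion, 2 with RIN, 2 with limma-voom, 150 with the DESeq2 Wald test and 33 with 1 surrogate variable. With single libraries left out they ran from 1 to 25, moving over 1.5 times in all but LRT control replicates 3 and 5. The count rose without HRT overload replicate 3 (16) or 4 (25), LRT control replicate 2 (17) or LRT overload replicate 2 (19), and fell in the others. The single exception for ENSRNOG00000015225 was the replicate block with RIN (−0.87, adjusted p = 0.294; range over settings 3.68e-11 to 0.294).

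For control muscle, 328 became 206 with no filter and 623 with the DESeq2 Wald test. With single libraries left out it ran from 154 to 495: 154, 194 and 215 without HRT control replicates 4, 5 and 6, and 495, 198, 176 and 211 without LRT control replicates 2, 3, 4 and 6. For overloaded muscle, 514 became 307 with no filter, 785 with RIN, 2153 by library totals, 1088 with the DESeq2 Wald test, 115 with the 2 groups alone and 1155 with 1 surrogate variable. Each of the 12 libraries left out moved it over 1.5 times: 176, 205, 1647, 1426, 332 and 217 without HRT overload replicates 1 to 6, and 304, 1547, 171, 263, 211 and 280 without LRT overload replicates 1 to 6. ENSRNOG00000056973 lost its call without HRT overload replicate 1, 2, 5 or 6 or LRT overload replicate 1, 5 or 6, with no filter and with the 2 groups alone (adjusted p up to 0.145).

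The score difference of 0.349 passed 0.05 with a minimum of 4-fold (0.512, exact permutation p = 0.039), and ran from 0.282 to 0.424 with single libraries left out. It passed without HRT overload replicate 3 (0.422) or 4 (0.42) or LRT overload replicate 2 (0.424). With the RIN slope removed the difference was 0.419 (permutation p = 0.0303). That slope was fitted once to the real groups and not again in each permutation, so this p may be too small. The correlation of responses was 0.954 over genes with a mean log2 CPM of at least 5. No named gene changed direction in its comparison under the settings tried. Library totals turned the majority of line differences in control and overloaded muscle from higher to lower in LRT.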

Other observations

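The overload score was defined after the data had been seen. In control libraries it was 0.0283 ± 0.0453 (SD, n = 6) in HRT and −0.0283 ± 0.0551 in LRT, and this difference of 0.0567 did not pass 0.05 (exact permutation p = 0.0866).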
